A study of Homo sapiens with 4 samples.

How the data were processed

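Single-cell RNA was measured in macrophages grown from blood monocytes of 2 healthy donors. Per the labels' protocols, monocytes were cultured with M-CSF (macrophage colony-stimulating factor) at 50 ng/ml for 5 days, and the macrophages were then kept in M-CSF with or without squalene at 1 mM. Cells were detached with trypsin, loaded on a 10X Chromium instrument, sequenced on a NovaSeq S2 flow cell and analysed in Seurat, per the labels' protocols. The submitters' processing notes name STAR and the human build hg38, with no versions. The sample titles abbreviate squalene as SQLE, which is also the symbol of a gene, squalene epoxidase. That symbol is used here for the gene only. The series' design text speaks of acne skin, but the samples analysed here are cultured macrophages.

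The deposited table holds natural log values, 1 column for each of 38 combinations of cluster, treatment and donor. Each value is a mean over the cells of that column of the natural log of 1 plus a whole-number count per cell. This was worked out from the values: the smallest value above 0 times the number of cells was ln 2 in all 38 columns, and 98.5% of 143092 low values were sums of ln 2, ln 3 and ln 4 within the tolerance of 1e-06 plus rounding. The counts appear to have been adjusted to a common depth per cell by the authors, because the sums of exp(value) minus 1 lay between 13056.8 and 16392.2 in every column. The method of that adjustment, the filters on cells and genes, the treatment of doublets, the clustering settings and any use of strand in counting are not given in the sources used here. Deposited labels place each of 4475 cells in 1 of 10 clusters and 1 of 4 samples. The table gives no total count per cell, so the sequencing depth is unknown. The planned comparison of depth and mitochondrial share per cell could therefore not be made.

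Values were divided by ln 2, which gives the mean log2(1 + corrected count) per cell. A sample's value is the mean over its clusters weighted by their cell numbers, which equals the mean over its cells. Differences are given on this scale, squalene minus M-CSF. They are not log2 fold changes of mean counts, and they understate the change of genes with low counts. Genes on the Y chromosome and XIST were left out of every table, which left 17803 genes. Genes with a mean of at least 0.1 over the 4 samples were tested, 9260 in all cells.

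The tests planned for counts were replaced, because the deposited values are log means. limma 3.58.1 in R 4.3.3 was fitted to the sample means with a trended prior variance and robust estimation, without a donor term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, two-sided. The p-values measure only the spread between cultures of 2 donors, with each gene's spread moderated toward that of genes of similar level. An exact permutation test of 2 against 2 samples cannot give a p below 0.333. The sample numbers are donor numbers, so they pair the samples by design. The labels describe the genotype as mixed and not demultiplexed, and how cells were assigned to donors is not stated, so every value per donor rests on the deposited assignment. The deviations of the same donor's samples from their group means had r = 0.417 across genes. A fit with the donor as a replicate block was an alternative. It has 1 residual degree of freedom, and the estimated prior degrees of freedom were infinite, so that a trend of variance on level sets every gene's error. Over all cells, the fit without the block has 2 residual and a median of 15.5 prior degrees of freedom. The prior degrees of freedom of the fits within clusters were not recorded.

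Both fits were tested on simulated data for the comparison of all cells, with 9260 genes, 200 of them changed, in 20 runs. Without the block, 51.6% of genes changed by 0.3, 97.9% of those changed by 0.6 and 99.4% of those changed by 1 were recovered, with 1.43% false calls. With the block the shares were 97.3%, 99.6% and 99.9%, with 9.55% false calls, above the nominal level. The simulated noise of each gene used the error that the block fit gave it, which follows that fit's trend. Spread of genes around the trend was not simulated, so these rates are a best case for the block. The gene list test was run on simulated data with 1 list shifted by -0.15. With the preset correlation the shifted list was called in 20 of 20 runs, along with 7 of 520 tests of unshifted lists. The simulated noise was independent between genes, so these runs do not test the preset correlation on lists whose members vary together. With an estimated correlation it was called in 0 of 20 runs, so at 4 samples that variant did not detect a shift of this size.

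Before the data were examined, 27 gene lists, 14 lists of cell type markers and the rule for named genes were fixed. Lists were tested with camera in limma (preset correlation 0.01) and, as alternatives, with an estimated correlation and with fry. Camera compares a list with all other genes tested. fry asks whether its members move, on balance, one way. Older symbols matched 2 list members. Named genes are the 12 largest rises and 12 largest falls past the threshold with the same direction in both donors, TREM2, and the 3 members with the smallest p of each list called by camera. The planned abundance floor in CPM was replaced by a mean of at least 0.5. Within clusters, the 5 largest rises and 5 largest falls were to be named in the cluster with the most cells, which was cluster 0. The same rule was applied to clusters 1 to 5 only after their values were seen.

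Tests within clusters used the 6 clusters with at least 20 cells in each sample. Whether a cluster's response differed from the others was tested on the cluster's value minus the mean of the other clusters tested, in each sample. These tests and the list tests within clusters were added after the data were seen. Every cluster had at least 2 of its 10 leading genes called between the treatments in some fit, so cluster shares were not compared between treatments. Alternatives comprised no filter, a mean of at least 0.5, median centring of each sample, the replicate block, each sample left out in turn, and all cells without cluster 6, 8 or 9. A further alternative weighted clusters as if the same number of cells came from each cluster in every sample. Coordinates are from GENCODE v29 on GRCh38, the assembly that hg38 names. Metallothionein, CCL3L1, CCL4L2, NCF1 and HLA genes share reads with near-identical copies and are uncertain. Genes that overlap a gene on the opposite strand, such as FGL2 within CCDC146 and IFIT1 within LIPA, are uncertain too. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.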

Results

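The series compared human macrophages cultured with M-CSF alone and with M-CSF plus squalene, a triterpene lipid of sebum and an intermediate of cholesterol synthesis. Each treatment was represented by 2 samples, 1 from each of the same 2 donors. The M-CSF samples held 1457 cells (donor 1) and 687 cells (donor 2), and the squalene samples 1595 and 736 cells. Levels are means over cells of log2(1 + corrected count), and the depth behind them is unknown. The authors' annotation divided the cells into 10 numbered clusters. Cluster 6 held 167 and 145 cells of the M-CSF samples and 0 of the squalene samples, which allows a share of up to 0.188% in donor 1 and 0.408% in donor 2 (3 cells, counting error only).

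The first comparison asked which genes differed between squalene-treated and untreated macrophages over all cells. Genes of chemokines and of a cytokine receptor were higher with squalene. PPBP, which encodes the neutrophil attractant CXCL7, rose from 0.39 ± 0.05 to 1.14 ± 0.01 (SD, n = 2 each), a difference of 0.76 ± 0.06 (SE, limma adjusted p = 1.13e-06). IL7R, the interleukin-7 receptor alpha chain, rose by 0.49 ± 0.06 (adjusted p = 0.000550). The monocyte attractant CCL2 rose by 0.73 ± 0.15, the neutrophil attractants CXCL2 and CXCL1 by 0.37 ± 0.07 and 0.36 ± 0.07, and SERPINB2, an inhibitor of plasminogen activators, by 0.25 ± 0.05 (adjusted p between 0.0420 and 0.0459). PPBP is also on the list of platelet markers and IL7R on that of T cell markers. No other platelet marker reached the filter. Without cluster 9, the cluster with T and NK cell markers, IL7R (0.49, limma adjusted p = 0.000667) and PPBP (0.76, 1.82e-06) kept their calls. In that fit 27 genes passed the test.

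Lower with squalene were FGL2 (fibrinogen-like 2), CCL18, a chemokine of alternatively activated macrophages, QPRT, an enzyme of NAD synthesis from tryptophan, and the interferon-stimulated gene ISG15. FGL2 fell from 1.15 ± 0.13 to 0.55 ± 0.07, a difference of -0.60 ± 0.07 (adjusted p = 0.000441). CCL18 fell from 1.08 ± 0.16 to 0.50 ± 0.01, a difference of -0.58 ± 0.07 (adjusted p = 0.000550). QPRT differed by -0.37 ± 0.04 (adjusted p = 0.000513) and ISG15 by -0.31 ± 0.05 (adjusted p = 0.0130). TREM2, a lipid-sensing receptor of macrophages, had 1.69 ± 0.10 in M-CSF and 1.47 ± 0.001 in squalene samples, a difference of -0.22 ± 0.08 that did not pass the test (adjusted p = 0.702). With the replicate block the TREM2 difference passed it (adjusted p = 0.000742), and without the cells of cluster 6 it was -0.05.

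**Figure D1:**
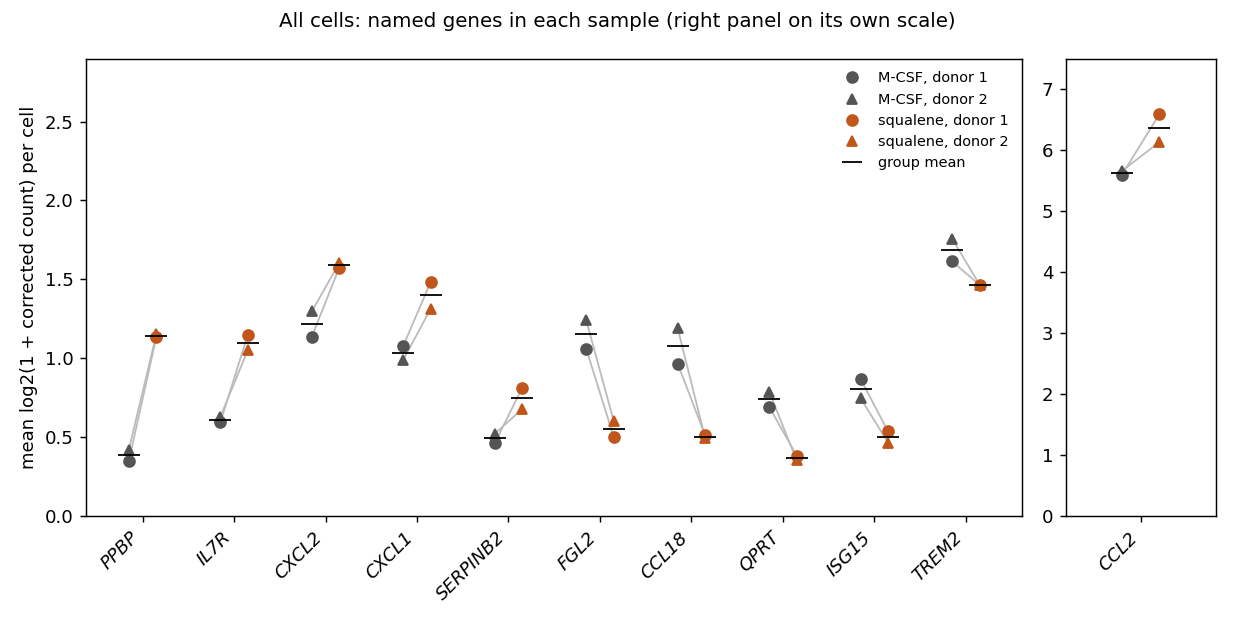
Mean log2(1 + corrected count) per cell (y axis) of the named genes (x axis) in each of the 4 samples, with CCL2 in a panel of its own scale. Circles are donor 1, triangles donor 2, grey M-CSF, orange squalene, lines join samples of a donor and dashes are group means; PPBP lies at 0.39 on average in M-CSF and 1.14 in squalene samples.

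In all, 28 of 9260 genes passed the threshold, 8 higher and 20 lower with squalene, and all 28 moved the same way in both donors. Passing the test with 2 samples per group favours the same direction in both donors, so this is not separate support. With the replicate block, 365 genes passed it (152 higher, 213 lower), among them all 28. With no filter 1 gene, PPBP, passed it, and without cluster 8 16 did. Leaving out M-CSF replicate 1 gave 145 genes, squalene replicate 1 90, M-CSF replicate 2 96 and squalene replicate 2 66. Leaving out the cells of cluster 6 gave 21 genes (3 higher, 18 lower), 17 of them among the 28. PPBP (0.72) and IL7R (0.47) then kept their calls, while CCL2 (0.54, adjusted p = 0.319), CXCL2 (0.28, 0.313), CXCL1 (0.30, 0.113) and SERPINB2 (0.19, 0.457) lost theirs. These 4 genes passed without cluster 6 when the replicate block was added (adjusted p = 0.000168, 1.96e-08, 9.90e-11 and 9.64e-06). FGL2 (-0.27), CCL18 (-0.30) and QPRT (-0.18) stayed past the threshold with smaller differences. Median centring also ended the calls of CCL2, CXCL2, CXCL1, SERPINB2 and ISG15 (adjusted p between 0.0551 and 0.107), as did leaving out cluster 8 (between 0.0791 and 0.110), while their differences stayed close to those over all cells (CCL2 0.74 in both, ISG15 -0.29 and -0.28). Matched cluster numbers gave 34 genes (13 higher, 21 lower), only 15 of them among the 28. There CCL2 (0.51, adjusted p = 0.0502), CXCL2 (0.25, 0.140), SERPINB2 (0.18, 0.177) and CCL4L2 (-0.24, 0.274) were among those that lost their calls. Single samples left out ended the calls of CCL2 (0.364 without squalene replicate 1), CXCL2 (0.206 without M-CSF replicate 1), CXCL1 (0.0859 without squalene replicate 1 and 0.114 without M-CSF replicate 2) and SERPINB2 (0.0681 without M-CSF replicate 1 and 0.137 without squalene replicate 1).

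On GRCh38 the 3 CXC chemokine genes lie on chromosome 4: CXCL1 at 73869393 to 73871242, PPBP at 73987038 to 73988197 and CXCL2 at 74097035 to 74099293. CCL2 (34255218 to 34257203) and CCL18 (36064280 to 36072032) lie on chromosome 17. IL7R lies on chromosome 5 (35852695 to 35879603), SERPINB2 on chromosome 18 (63871692 to 63903890), QPRT on chromosome 16 (29679008 to 29698699), ISG15 on chromosome 1 (1001138 to 1014540) and TREM2 on chromosome 6 (41158506 to 41163186). FGL2, on chromosome 7 (77193371 to 77199848), overlaps CCDC146 on the opposite strand.

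Among the fixed gene lists, the interferon-stimulated genes were lower with squalene. Of 17 members tested 7 fell and none rose, 13 fell adjusted over the list alone, and all 17 differences were negative (median -0.13, camera adjusted p = 2.55e-30). MX1 fell by 0.17, XAF1 by 0.24 and IFIT1 by 0.11, with adjusted p of 0.000631, 0.00116 and 0.000941. With an estimated correlation the list was not called (adjusted p = 0.577). Without cluster 8, which is led by such genes, the list's camera adjusted p was 8.49e-21, while ISG15 (-0.28) and MX1 (-0.14, adjusted p = 0.254) lost their calls with differences a little smaller. With the replicate block 14 of the 17 fell.

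The 12 genes tested of the list for antigen presentation by MHC class II, which includes costimulatory receptors, all had negative differences (median -0.18, camera adjusted p = 6.97e-09), but 0 passed the test singly and 1 fell adjusted over the list alone. HLA-DMA differed by -0.24, HLA-DPA1 by -0.25 and CD74 by -0.30. The list was not called with an estimated correlation (adjusted p = 0.577) or without M-CSF replicate 1 (0.0913), and 10 of the 12 fell with the replicate block. Without cluster 6 its median was -0.07 (0.0314), HLA-DMA differed by -0.11, HLA-DPA1 by -0.12 and CD74 by -0.18, and with the block 0 of the 12 fell. The list of metallothioneins, metal-binding proteins, which also holds the zinc transporter SLC30A1, had a median difference of -0.33 over 8 genes (camera adjusted p = 0.000445), with 0 members called over all genes or adjusted over the list alone. MT1E differed by -0.32, MT1X by -0.40 and MT1F by -0.14. MT1E and MT1X passed without cluster 6 (-0.48 and -0.60, adjusted p = 0.0192 and 0.0371). They differed by -0.51 and -0.66 without M-CSF replicate 2, but by -0.13 and -0.15 without M-CSF replicate 1. MT1E differed by -0.40 without squalene replicate 2. The list was not called with an estimated correlation (adjusted p = 0.577) or without squalene replicate 1 (0.0515), and its direction turned without M-CSF replicate 1 (0.659). Without cluster 6 its median was -0.54 (1.75e-17).

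Heat shock genes (12 tested, median -0.11, camera adjusted p = 0.00359), nuclear genes of oxidative phosphorylation (20 tested, median -0.07, 0.00998) and ribosomal protein genes, fixed as a sign of RNA quality (20 tested, median -0.12, 0.00243), had 0 members called, also adjusted over the list alone. With an estimated correlation their adjusted p was 0.718, 0.577 and 0.577. With the replicate block 3 heat shock genes fell, HSPH1, HSPE1 and HSPD1 (limma adjusted p = 0.00821, 0.00264 and 0.0219), and 6 adjusted over the list alone. In that fit 0 genes of oxidative phosphorylation and 1 ribosomal protein gene fell. HSPH1 differed by -0.19, HSPE1 by -0.23, HSPD1 by -0.17, CYC1 by -0.12, UQCRQ by -0.14, SDHD by -0.10, RPS18 by -0.20 and RPS2 by -0.17. Without cluster 6 the heat shock (adjusted p = 0.593) and oxidative phosphorylation (0.232) calls were lost. Their medians were then -0.04 and -0.01, HSPH1 differed by -0.04 and HSPE1 by -0.10, and with the block 0 members of either list fell. The heat shock call was also lost without M-CSF replicate 2 (0.389) or squalene replicate 2 (0.0984), and that of oxidative phosphorylation without M-CSF replicate 1 (0.493), M-CSF replicate 2 (0.0834) or squalene replicate 2 (0.495). The ribosomal call was lost without M-CSF replicate 1 (0.821) or squalene replicate 2 (0.0858). The list for alternative activation in M-CSF was lower (14 tested, median -0.05, camera adjusted p = 0.00217). CCL18 fell, and 1 member rose and 2 fell adjusted over the list alone. CD163 differed by 0.49, opposite to the list, and CD200R1 by -0.19. CD163 passed with the replicate block (adjusted p = 3.15e-09). CD200R1 passed after median centring (0.0472) and with the block (4.66e-25), and without cluster 6 its level was below the filter. The list's call was not held with an estimated correlation (adjusted p = 0.577) or without cluster 6 (0.0751).

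The proinflammatory cytokines and chemokines were higher as a list (20 tested, median 0.06, camera adjusted p = 9.30e-05). CCL2, CXCL1 and CXCL2 rose and CCL4L2 fell (-0.33, adjusted p = 0.00178), and adjusted over the list alone 6 rose and 3 fell. Scavenger and phagocytic receptors were higher (18 tested, median 0.10, camera adjusted p = 0.000752), with 0 called over all genes and 3 rising adjusted over the list alone. CD163, the haemoglobin scavenger receptor, differed by 0.49, FCGR1A by 0.16 and COLEC12 by 0.16. Neither list was called with an estimated correlation (adjusted p = 0.577 for both). The proinflammatory call was lost without squalene replicate 1 (0.0633). With the replicate block 7 receptors rose and 2 fell, and 7 proinflammatory genes rose and 4 fell. With the block and without cluster 6, 2 receptors rose and 1 fell, and FCGR1A (0.10) and COLEC12 (0.11) lost the calls they had with the block (adjusted p = 0.0694 and 0.0505).

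The list of lipid-associated TREM2 macrophage genes was higher (18 tested, median 0.13, camera adjusted p = 0.00541). Its only member past the test, FABP4, a fatty acid carrier, fell (-0.17, adjusted p = 0.00274), and 2 rose and 2 fell adjusted over the list alone. FABP4 differed by -0.08 without cluster 6 (0.0498) and by -0.09 with matched cluster numbers, and it lost its call with no filter (0.163). The lipid droplet protein PLIN2 differed by 0.38 and CHI3L1 by 0.12, and both passed with the replicate block (5.19e-08 and 4.36e-10), where 4 members rose and 3 fell. With an estimated correlation the adjusted p was 0.577, after median centring 0.212 and without M-CSF replicate 1 0.0529. Iron handling genes (10 tested, median 0.08, camera adjusted p = 0.000278, 1 rising adjusted over the list alone) included CD163, SLC11A1 (0.23) and HFE (0.04). SLC11A1 passed with the replicate block (0.0113), and it differed by 0.34 without M-CSF replicate 1, by 0.11 without M-CSF replicate 2 and by 0.11 without cluster 6. HFE differed by 0.03 without M-CSF replicate 1. Immediate early genes, fixed as a list for cell dissociation, were higher too (16 tested, median 0.06, 0.00341, 0 called). They included FOS (0.29), FOSB (0.30) and DUSP1 (0.25), which all passed with the replicate block (0.00137, 1.65e-14 and 0.00107), where 4 members rose. Without M-CSF replicate 1 FOS differed by 0.17, FOSB by 0.13 and DUSP1 by 0.01, and without M-CSF replicate 2 by 0.41, 0.47 and 0.49. Without squalene replicate 1 FOSB differed by 0.41. FOSB differed by 0.20 and DUSP1 by 0.13 without squalene replicate 2. With an estimated correlation their adjusted p was 0.577 and 0.752. The iron call was lost without M-CSF replicate 2 (0.389). The immediate early call was lost without squalene replicate 2 (0.943), and its direction turned without M-CSF replicate 1 (0.871).

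**Figure D2:**
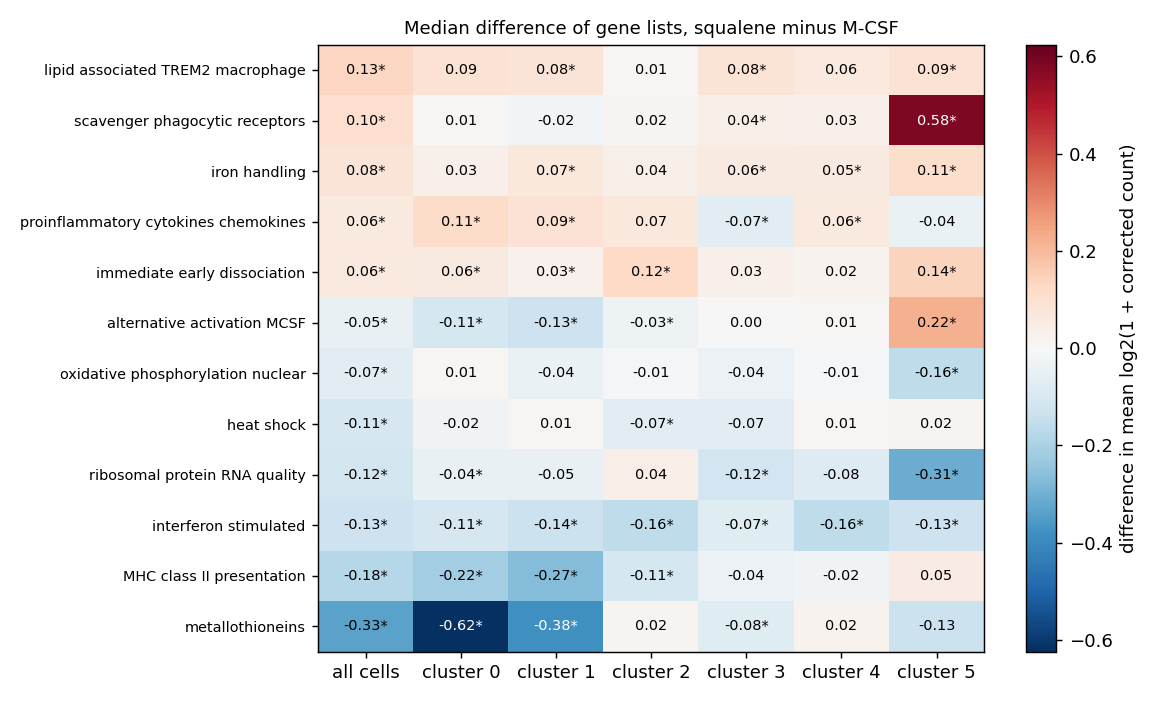
Median difference in mean log2(1 + corrected count), squalene minus M-CSF, of the 12 gene lists called over all cells (rows), in all cells and in clusters 0 to 5 (columns), with red above and blue below 0. A star marks a camera adjusted p under 0.05 with the preset correlation. The interferon-stimulated list is below 0 in every column, and the scavenger receptors reach 0.58 in cluster 5.

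The other 15 lists were not called (camera adjusted p from 0.0523 to 0.813). They comprised cholesterol biosynthesis, LXR targets, fatty acid synthesis, PPAR targets, lysosomal hydrolases, NF-kappaB feedback, complement, antimicrobial and oxidative burst genes, NRF2 targets, the unfolded protein response, hypoxia and glycolysis, matrix remodelling, cell cycle, apoptosis and mitochondrially encoded genes. Of 22 cholesterol biosynthesis genes 0 passed the test, also adjusted over the list alone (median -0.01), and SQLE, the gene of squalene epoxidase, differed by -0.01 ± 0.04. Without cluster 6 that list was lower (adjusted p = 0.0174). FABP4 was the only gene of these 15 lists past the test without the block, as a PPAR target. With the replicate block 2 PPAR targets rose and 2 fell. Of lysosomal hydrolases, complement, and hypoxia and glycolysis, 2 genes each then rose, and 2 apoptosis genes fell. The others of these lists had at most 1 gene rising and 1 falling. For PPAR targets the median and camera pointed down and the mean up, and for complement the median pointed down and the mean and camera up. With the replicate block matrix remodelling was called higher (0.0404), as it was without squalene replicate 1 (0.0365). Lysosomal hydrolases were called higher without cluster 8 (0.0307) or squalene replicate 2 (0.0196), and LXR targets without M-CSF replicate 1 (0.0137) or squalene replicate 2 (0.00366). NRF2 targets were called higher without M-CSF replicate 1 (0.0498) or squalene replicate 2 (9.83e-06) and lower without squalene replicate 1 (0.00927). Without squalene replicate 2, antimicrobial genes were called higher (0.0432) and apoptosis genes lower (0.0489). Of the cell type markers, IL7R and PPBP were the only ones past the test. No marker of NK, B, plasma, erythroid or proliferating cells reached the filter. The lists for monocytes (6 tested), macrophages (10), dendritic (1), plasmacytoid dendritic (2), neutrophil (1), fibroblast (1) and endothelial cells (2) had 0 called over all genes. Adjusted over the list alone, 1 macrophage and 1 fibroblast marker rose and 1 T cell marker fell. With the replicate block, beside IL7R and PPBP, 2 monocyte markers, 2 macrophage markers and 1 fibroblast marker rose. In that fit 1 monocyte marker and 1 T cell marker fell.

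The second comparison asked for the response within each of the 6 clusters that had enough cells. In cluster 0, which had the most cells (1068), metallothioneins were lower and PPBP and CXCL1 higher with squalene. MT2A fell from 3.82 ± 0.35 to 2.84 ± 0.18 (-0.97 ± 0.13, adjusted p = 0.000128). MT1X fell by 0.88, MT1G by 0.80, MT1H by 0.73 and MT1E by 0.52. Of the 8 genes of the metallothionein list 7 fell, all but SLC30A1 (camera adjusted p = 7.90e-42, 0.639 with an estimated correlation). The list was called lower in 3 of 6 clusters. In clusters 2, 4 and 5 it was not called, with medians of 0.02, 0.02 and -0.13. PPBP rose by 0.68 ± 0.06 (adjusted p = 4.23e-08), CXCL1 by 0.42 ± 0.08, SERPINB2 by 0.33 ± 0.07 and IL7R by 0.31 ± 0.06. In total 18 genes passed the test, 5 higher and 13 lower, against 89 with the replicate block, 51 higher and 38 lower. The count was 9 without squalene replicate 1, 37 without M-CSF replicate 2 and 7 without squalene replicate 2. Ribosomal protein genes (median -0.04, 0.0311) and immediate early genes (median 0.06, 0.0113) were called lower and higher there, both with an adjusted p of 0.918 with an estimated correlation.

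Further genes in clusters 1 to 4 were chosen after their values were seen. In cluster 1, SPP1 (osteopontin) rose by 1.09 ± 0.14, CCL7 by 0.78 ± 0.12 and the cystine transporter SLC7A11 by 0.72 ± 0.12, while MS4A6A fell by 0.50 ± 0.09. SPP1 differed there by 0.73 in donor 1 and by 1.45 in donor 2, and CCL7 by 1.28 and 0.28. The limma SE, which borrows from other genes, understates this spread. In cluster 2, the neutrophil cytosolic factor NCF1 fell by 0.88 ± 0.14 and FCN1 by 0.67 ± 0.09. In cluster 3, SPP1 rose by 1.34 ± 0.13, the scavenger receptor MARCO by 0.74 ± 0.09 and CD163 by 0.52 ± 0.09, while CCL13 fell by 0.58 ± 0.11. Ribosomal protein genes were lower there as a list (median -0.12, camera adjusted p = 2.56e-05, 0.697 with an estimated correlation). In cluster 4, CCL2 rose by 0.87 ± 0.14. IL7R rose in 6 of 6 clusters and PPBP in 5. The interferon-stimulated list was lower in 6 of 6 clusters. None of the 51 list calls among 162 tests within clusters held with an estimated correlation (adjusted p from 0.639 to 0.918).

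The number of genes past the test was 29 in cluster 1 (11 higher, 18 lower), 6 in cluster 2, 31 in cluster 3 and 5 in cluster 4. With the replicate block it was 110, 64, 18 and 37. Median centring gave 8 in cluster 1 (4 higher, 4 lower) and 29 in cluster 2 (7 higher, 22 lower). At an unadjusted p under 0.05 the counts were 323, 344, 366 and 319. Without squalene replicates 1 and 2 in turn, the count in cluster 1 was 11 and 15. In cluster 2 it was 1 without M-CSF replicate 1, 80 without squalene replicate 1, 0 without M-CSF replicate 2 and 10 without squalene replicate 2. In cluster 3 it was 49, 11, 156 and 10 in the same order, and in cluster 4 it was 8 without either M-CSF replicate. CCL13 and CCL18, which fell in 4 and 3 of the 6 clusters, had levels of 3.33 and 2.55 in cluster 6, against 0.60 and 0.78 in the other M-CSF cells.

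Cluster 5 had 337 genes past the test, 151 higher and 186 lower with squalene, all in the same direction in both donors, which passing the test favours. After median centring 188 were higher and 162 lower. The genes named here were chosen after their values were seen. SPP1 rose from 2.81 ± 0.21 to 5.21 ± 0.37 (2.39 ± 0.17, adjusted p = 3.45e-16), the chemokine CCL7 by 1.84 ± 0.17, and the receptors MARCO, MRC1 and FCGR2A by 1.67 ± 0.13, 1.52 ± 0.14 and 1.44 ± 0.14. CCL4L2 fell by 1.64 ± 0.21, the autophagy protein gene MAP1LC3A by 1.52 ± 0.17, CCL4 by 1.45 ± 0.17, the C-type lectin CLEC4E by 1.42 ± 0.13 and the glutamate transporter SLC1A3 by 1.42 ± 0.13. In donors 1 and 2 the differences were -1.11 and -2.16 for CCL4L2, -1.91 and -1.14 for MAP1LC3A and -0.90 and -1.99 for CCL4. The limma SE understates this spread. CLEC4E (-1.49 and -1.35) and SLC1A3 (-1.38 and -1.46) differed less between donors. Of 17 scavenger and phagocytic receptors 13 rose and 1, OLR1, fell (camera adjusted p = 9.97e-24, 0.639 with an estimated correlation). Of 14 NF-kappaB feedback genes 6 fell and 1 rose (1.37e-09, 0.639 with an estimated correlation), with NFKBIA at -0.94 and TNFAIP3 at -0.92. Of 20 ribosomal protein genes 4 fell (1.10e-06, 0.639 with an estimated correlation). PPBP differed by 2.21 ± 0.38 but did not pass the test (adjusted p = 0.0954). Donor 2 contributed 30 M-CSF and 41 squalene cells to this cluster. Without M-CSF replicate 2 the count was 152, and with no filter 102.

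**Figure D3:**
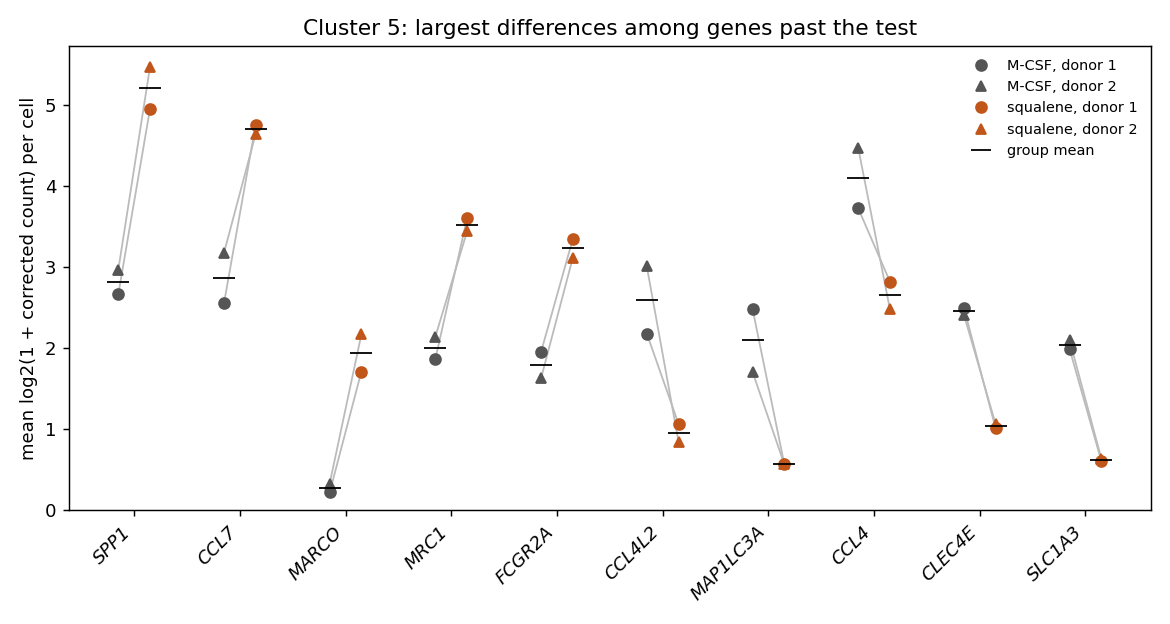
Mean log2(1 + corrected count) per cell (y axis) in cluster 5 of the 5 genes with the largest rise and the 5 with the largest fall among genes past the test with a mean of at least 0.5 (x axis), in each of the 4 samples. Circles are donor 1 and triangles donor 2, grey is M-CSF and orange squalene, lines join samples of a donor, and dashes are group means. SPP1 lies at 2.66 and 2.96 in the M-CSF and at 4.95 and 5.47 in the squalene samples.

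The last comparison set the responses of the donors side by side, as a description with no test. Across 9260 genes, which are not independent replicates, the differences of donor 1 and donor 2 had Pearson r = 0.370 and Spearman rho = 0.235. The SPP1 difference over all cells was 0.78 in donor 1 and 1.71 in donor 2, and it did not pass the test (limma adjusted p = 1.00). Neither that fit nor the fits within clusters had a donor term. Within clusters SPP1 rose in 3 of 6 (differences from 0.60 to 2.39 over the 6). The PPBP difference was 0.78 in donor 1 and 0.73 in donor 2.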

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

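The tests of explanations and the tests of a cluster against the others were chosen after the results they bear on had been seen. Cluster 6 held M-CSF cells only, 312 in all. If squalene cells of this kind had been placed in another cluster, some squalene column would lie well along the way from other M-CSF cells to cluster 6 on its 20 leading genes. The highest lay at -1.56% of the way, which argues against a column made up largely of such cells. Each column is a mean over its cells, so a small number of them would not show. Nor would counterparts that lost these genes under squalene. No label names another culture mixed into both M-CSF libraries, and the count of 0 cluster 6 cells in the squalene libraries, which is the pattern itself, does not test for one. An effect of squalene on these cells stays open and untested.

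Most of the genes that lead cluster 6 were also lower with squalene in clusters 0 to 4. Free RNA from cluster 6 cells in the M-CSF libraries may contribute. The M-CSF excess of 17 of 20 genes was present in both donors. Over these 17 only, the median donor 2 to donor 1 ratio was 1.47 (quartiles 0.916 and 1.81), against 1.84 for the share of cluster 6 cells. F13A1 (0.21 in donor 1, -0.18 in donor 2) and MS4A6A (0.34 and -0.19) had an excess in donor 1 only. CLEC4A had -0.02 and 0.01. Free RNA should also give each cluster a similar excess, but cluster 5 had a median of -0.00744% of the cluster 6 level against 6.63% in cluster 3, as a response within the clusters would allow. That median mixes genes such as QSOX1 (-17.9%) and MS4A6A (-7.18%) with others that had an excess there. ALOX15 and CCL26, listed at 0 in the squalene cells, had 3.99% and 4.57% in cluster 5, against 3.32% to 7.69% in clusters 0 to 4. A share below 0 was counted as beyond the bound of 3 times, a reading fixed after the value was seen that rests on cluster 5 (ratio 2.38 among clusters 0 to 4), so both explanations stay open.

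Cluster 5 had by far the most genes called, 337. Noise from the few cells of donor 2 is argued against by the correlation of both donors' differences across genes, r = 0.555, against 0.0995 to 0.218 in the other clusters. The cells grouped as cluster 5 may lie at different positions between cluster 4 and clusters 0 to 3 under the treatments. The cluster 5 difference had r = 0.319 with that axis across all genes tested (clusters 0 to 3: -0.187 to -0.0244), between the bounds set for and against, and r = 0.556 across the 337 genes called, which were selected for that difference and have no bound of their own, so this cannot be told apart from a change within the same cells. A response of these cells to squalene stays open.

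The response of 176 genes in cluster 5 (79 more positive, 97 more negative) differed from the mean of the other clusters tested. The corresponding numbers were 15 in cluster 1, 7 in cluster 2, and 1 each in cluster 0 (SPP1) and cluster 3 (CCL7). Some lists were called in opposite directions in different clusters, with camera tests of the difference from the other clusters. The mean of the other clusters includes cluster 5, so a large response there also moves the contrasts of the other clusters. The NF-kappaB feedback list was higher in cluster 0 (adjusted p of the difference 1.57e-07) and lower in cluster 5 (2.21e-06). Its median was 0.06 in cluster 0, with 0 of 13 genes called, and -0.32 in cluster 5. In cluster 1, where the list was not called, the contrast was higher too (6.63e-06). NRF2 targets were higher in cluster 1 (1.80e-08) and lower in cluster 5 (5.95e-06). The alternative activation list was lower in clusters 0 (0.00533), 1 (1.60e-05) and 2 (0.0170) and higher in cluster 5 (5.46e-07). The proinflammatory list was higher in cluster 0 (0.000958) and lower in cluster 3 (7.23e-09), where the ribosomal protein list was lower too (camera adjusted p = 2.56e-05 within the cluster). These used the preset correlation, and none of the calls within clusters held with an estimated correlation (adjusted p from 0.639 to 0.918). MT1F over all cells differed by -0.40 in donor 1 and by 0.11 in donor 2, a difference between donors that was not tested.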

How the results depend on the processing

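Median centring, the mean of at least 0.5 and the fits without cluster 6 or 8 were chosen after the data were seen. Not run for want of counts were the RLE factors, the DESeq2 test, the CPM filters, thinning, the range of UMIs per cell and the cell depth comparison; cluster shares were not compared. The 28 genes over all cells became 1 with no filter, where 17803 genes were tested, 12 with a mean of at least 0.5, 16 without cluster 8, 365 with the replicate block, 241 with the block and without cluster 6, and 66 to 145 when a sample was left out. With matched cluster numbers 34 genes passed, 15 of them among the 28. The 12 called lists became 0 with an estimated correlation and 0 with fry. In clusters 0 to 5 no filter left 2, 3, 0, 2, 8 and 102 genes. The replicate block gave 89, 110, 64, 18 and 37 in clusters 0 to 4. Median centring gave 8 in cluster 1 and 29 in cluster 2. Leaving out a sample gave 7 to 37 in cluster 0, 11 to 43 in cluster 1, 0 to 80 in cluster 2, 10 to 156 in cluster 3, 6 to 8 in cluster 4 and 152 to 379 in cluster 5. A fit with a sample left out assumes that the lone sample varies like the others, so more calls there are not stronger evidence. Beyond the fewer or more genes tested, the cause was not tested. The correlation of donor responses was 0.364 among genes with a mean of at least 0.5.

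Some directions turned, each time for a list or gene not called in the turned direction except NRF2 targets without squalene replicate 1 (adjusted p = 0.00927). Antimicrobial genes turned after centring (0.767) and without cluster 6 (0.204), the unfolded protein list without cluster 6 (0.656). With samples left out in turn, the MT1F difference lay between -0.359 and 0.0729. Adjusted p of the lists that turned lay at 0.204 to 0.572 for NF-kappaB feedback, 9.74e-18 to 0.659 for metallothioneins, 9.38e-09 to 0.943 for immediate early genes, 0.205 to 0.759 for cholesterol biosynthesis, 0.00366 to 0.431 for LXR targets, 0.0432 to 0.26 for antimicrobial genes, 9.83e-06 to 0.735 for NRF2 targets, 0.0616 to 0.531 for mitochondrial genes and 0.0858 to 0.965 for complement. The turned values were 0.557 and 0.572, 0.659, 0.871, 0.389 and 0.759, 0.260 and 0.431, 0.186 and 0.260, 0.00927 and 0.735, 0.521 and 0.531, and 0.542 in that order, and 0.0729 for MT1F. Of the 12 called lists, interferon-stimulated genes and scavenger receptors kept their call with the replicate block, after median centring, without cluster 6 or 8 and with each sample left out, but not with the estimated correlation or fry; the other alternatives were not run for lists. Unknown depth limits what can be said of genes with low levels.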

Other observations

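The observations below were chosen after the values were seen. In cluster 2, whose leading genes are metallothioneins, genes of lysosomal hydrolases and acidification were lower with squalene as a list (27 tested, median -0.10, camera adjusted p = 7.58e-07, and 0.639 with an estimated correlation). None passed the test singly, and 1 rose and 4 fell adjusted over the list alone. The list's difference from the other clusters had an adjusted p of 2.44e-14. CTSH, a lysosomal protease, differed by -0.39 and CYBB, the catalytic subunit of the phagocyte NADPH oxidase, by -0.50, both short of the threshold. The antimicrobial and oxidative burst list was lower there too (9 tested, adjusted p = 9.73e-08, and 0.639 with an estimated correlation), with NCF1 its only member past the test.

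In cluster 1, NRF2 targets were higher as a list (16 tested, median 0.12, camera adjusted p = 2.33e-05, and 0.733 with an estimated correlation), with SLC7A11 the only member past the test. MHC class II genes were lower (12 tested, median -0.27, adjusted p = 1.31e-15, and 0.639 with an estimated correlation), where HLA-DPA1 fell by 0.45 and 9 fell adjusted over the list alone. ALOX15 was listed at 0 over all cells of both squalene samples and had a mean of 0.56 ± 0.26 (SD, n = 2) in the M-CSF samples, a difference that did not pass the limma test (adjusted p = 1.00). It is a leading gene of cluster 6, which held M-CSF cells only, and without that cluster the difference was -0.23.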
